A study of Rattus norvegicus with 12 samples.

How the data were processed

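Messenger RNA of the rat prostate was measured on 12 Agilent microarrays, 3 in each of 4 groups. Per the labels, male rats of 10 weeks had either a sham operation or a partial obstruction of the bladder outlet, made by tying a rubber ring around the urethra close to the bladder. They received vehicle (0.1% Tween 80) or Eviprostat, a phytotherapeutic preparation used for benign prostatic hyperplasia, at 18 mg/kg per dose and 36 mg/kg per day, for 5 days. Each group held 5 or 6 animals, and RNA was taken from tissue pooled within a group. The 3 arrays of a group are called biological replicates in the labels, while the labelling protocol speaks of pooled tissue. Because tissue was pooled per group, the p-values measure only the spread between arrays and not that between animals. The labels also describe dosing of the sham animals as starting 5 days after the operation and dosing of the obstructed animals from the day after it, so operation and time since surgery were not separated.

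Every array carried RNA of its own group in Cy5 (red) and sham/vehicle RNA in Cy3 (green), with no dye swap. On the 3 sham/vehicle arrays both dyes carried sham/vehicle RNA, so a group was compared with those arrays rather than with a log ratio of 0, which removes a dye effect common to the arrays. The amount of RNA labelled was 1500 ng for sham/vehicle and 300 ng for each other group. Per the file headers the arrays lay on 3 slides of 4 arrays, 1 array of each group per slide, and the slide number followed the replicate number. Slide 1 was scanned on another day than slides 2 and 3. A group always had the same position on its slide, so position and group cannot be told apart.

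The values used are the spot and local background intensities of both channels, which the authors deposited as written by Agilent Feature Extraction 9.5.1.1, per the file headers. Per the same headers, the processed intensities were background-subtracted, detrended and dye-normalized with linear and LOWESS terms, and the deposited log10 ratio is red over green processed signal. The value table of the whole series was set against the scanner values and equals that log10 ratio at every spot, with a largest difference of 0. Its scale and direction are therefore known, and it was not centred further. Its median was 0 on 9 arrays and -0.00886, -0.00115 and -0.00348 on obstruction/vehicle replicates 1, 2 and 3. Genome positions are those of the array design on rat build rn3, per the file headers.

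From the raw intensities the background was corrected with normexp and an offset of 50, and log2 ratios of Cy5 over Cy3 were normalized within each array by loess, in limma 3.58.1 under R 4.3.3, with statmod 1.5.0 and data.table (version 1.17.8; figures by matplotlib 3.10.9 in Python 3.11.15). Control spots and spots that the scanner software marked as outliers had no weight in loess and were then left out, and saturated spots were kept. Spots of one probe were averaged. Of 41012 probes, 36098 were kept because Cy5 was well above background on at least 3 of the 12 arrays. Probe names were updated through gene accessions and symbols of the rat reference annotation GRCr8, used for names only. Of all probes, 10674 were named through an accession, 5582 had a current symbol, 3823 were renamed through a synonym, 3329 kept the array's symbol and 17604 had no gene name. The kept probes with a name stood for 17096 genes, and a gene was represented by its brightest kept probe.

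Signal limits what the arrays can show. The share of spots with Cy5 well above background ran from 71.0% on obstruction/Eviprostat replicate 1 to 88.4% on obstruction/vehicle replicate 3, and median Cy5 intensity from 401 to 677 on the same 2 arrays. The Cy5 signal was dimmer on the 4 arrays of slide 1. The number of arrays limits the precision of each difference. Where a probe was not well above background on any array of a group, its difference is given as a lower bound: the brighter group's mean Cy5 level after loess and Aquantile normalization, against the mean over the dimmer group's arrays of the lowest level among probes well above background or the probe's own level, whichever was higher. Such bounds come from Cy5 alone, without the Cy3 channel of the ratio, so they are another measure than the fitted log ratio and exceed it for the genes named; the adjusted p beside them belongs to the fitted ratio. They remain open to dye bias.

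Differences were tested with limma (lmFit and eBayes) in one fit of all 12 arrays, with 1 mean per group, 8 residual degrees of freedom and Benjamini-Hochberg adjustment over the kept probes at a threshold of 0.05. The comparisons were obstruction/vehicle against sham/vehicle, obstruction/Eviprostat against obstruction/vehicle, sham/Eviprostat against sham/vehicle, obstruction/Eviprostat against sham/Eviprostat, and the difference between the effects of Eviprostat in obstructed and in sham animals. For genes that obstruction changed at least 2-fold, the sign and size of the change under Eviprostat were counted. Errors given with log2 differences are standard errors of the fit, with n = 3 arrays per group.

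The comparisons, the tests, 34 gene lists (19 of processes and 15 of cell types), the rule for naming genes and most of the alternatives were chosen before the data were examined; the alternatives added later are named as such below. Lists were tested with camera at its preset correlation of 0.01 between genes, with camera at an estimated correlation, and with fry. The lists hold 711 genes of which 24 are in more than 1 list. Members past the threshold were counted over all probes tested and, again, adjusted over the list alone. The genes named are, for each of the 3 comparisons with vehicle controls, the 10 with the largest rise and the 10 with the largest fall among genes past the threshold whose groups did not overlap and that were well above background in the higher group; up to 4 members of each list with the smallest adjusted p; and 12 genes fixed by name, of which 11 were measured under that name. Some genes of the first and second kind were left out for length.

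Arrays with the same replicate number shared a slide, and they deviated from their group means together. Over all probes, these deviations correlated at 0.536 to 0.779 for replicate 1, 0.155 to 0.575 for replicate 2 and 0.376 to 0.556 for replicate 3, against -0.702 to 0.557 between arrays of different number. All negative values were between replicate 1 and replicates 2 or 3. Arrays of replicate 2 correlated with arrays of replicate 3 at 0.089 to 0.557. The deviations therefore set slide 1, scanned on another day, apart more than they pair arrays by single replicate numbers. Fits with the replicate number (the slide) or the scan day as a block were run beside the one without a block. Replicates 2 and 3 of a group had the same raw Cy5 value at 1 or 2 spots only, and the log ratios of arrays of one group correlated at 0.033 to 0.864, lowest between sham/vehicle replicates 1 and 2.

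The limma step was tested on simulated data made from the spread of the 36098 probes in the obstruction comparison. It called 40.3% of probes changed 1.5-fold, 82.1% of those changed 2-fold and 97.0% of those changed 4-fold, and 6 unchanged probes among 152 calls. A simulated list of moved genes was called by all 3 list tests, with 0 other lists called. The simulated genes were drawn independently of each other and without a slide effect. This check therefore could not show false list calls that correlated genes give.

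The alternatives were the scanner software's log ratio, the series' value table, no background subtraction, a normexp offset of 10, median centring in place of loess, Aquantile between arrays, Cy5 alone as a 1-colour measurement, no filter and a stricter filter on dim probes, only the 6 arrays compared, the replicate number, the slide or the scan day as a block, array weights, an intensity trend with a robust prior, each array left out in turn, a fold minimum, and obstruction/vehicle ratios against 0. The background fit was found to be pulled away on sham/vehicle replicate 1, obstruction/vehicle replicate 2 and obstruction/Eviprostat replicate 1 by 19 spots whose local background exceeded 2 times the array's median. After seeing the data, a background fit without those 19 spots, with and without the block, a fit without the 3 arrays, and a fit of slides 2 and 3 alone were added.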

Results

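The series holds 12 arrays of rat prostate RNA, with 3 arrays each for sham-operated rats given vehicle, sham-operated rats given Eviprostat, rats with partial bladder outlet obstruction given vehicle, and obstructed rats given Eviprostat. The prostates were removed on the day after 5 days of treatment, 2 h after the last dose. The data address what obstruction changes in the prostate and what Eviprostat does to those changes. The measurement is the log2 ratio of Cy5, the group's RNA, to Cy3, sham/vehicle RNA, after background correction and loess. Between 71.0% and 88.4% of spots were well above background in Cy5 on an array.

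Obstruction was first compared under vehicle. As lists, macrophage, extracellular matrix, complement, class II presentation, hypoxia, smooth muscle and seminal vesicle genes were higher in the obstructed rats than in sham rats and skeletal muscle genes lower, with the tests given below. These list calls held with an estimated correlation, but none did with the replicate block as well. Il1b, which encodes interleukin-1 beta, was 12.7-fold higher (log2 difference 3.66 ± 0.14, adjusted p = 1.49e-08 by limma; probe at chromosome 3, 116870289 to 116870348 on rn3). Col1a1, a chain of type I collagen, was 8.40-fold higher on its brightest probe (3.07 ± 0.19, adjusted p = 8.9e-07; chromosome 10, 83652547 to 83652606) and rose less on its other probes. Svs5, a seminal vesicle secretory protein, was 219-fold higher (7.77 ± 0.35, adjusted p = 6.58e-08; chromosome 3, 155171865 to 155171924), with Cy5 saturated on 2 of the 3 obstruction/vehicle arrays. All 3 genes were higher on each of the 3 slides. Cy5 alone gave larger differences for genes dim in sham/vehicle, 8.59 for Il1b and 12.82 for Svs5.

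Among inflammatory mediators, the neutrophil attractants Cxcl2 and Cxcl1 rose by 7.28 ± 0.21 (adjusted p = 1.26e-09) and 4.84 ± 0.42 (adjusted p = 1.35e-05). Ccl2, a monocyte attractant, rose by 3.95 ± 0.51 (adjusted p = 0.000316), with 2.26 on slide 2 and 4.75 and 4.84 on slides 1 and 3. Il1rn, the interleukin-1 receptor antagonist, rose by 5.31 ± 0.24 on its brightest probe and by 1.58 on its other kept probe. Of 30 chemokine genes measured, 14 were higher and 0 lower (18 and 0 when adjusted over the list alone). The camera call of this list (adjusted p = 2.72e-10) was lost with an estimated correlation (adjusted p = 0.0801). Of 24 cytokine genes 11 were higher and 0 lower (14 and 0 adjusted over the list alone), with adjusted p = 1.17e-05 by camera and adjusted p = 0.0748 with an estimated correlation. Nos2, the inducible nitric oxide synthase, rose by 1.33 ± 0.24 (adjusted p = 0.00304). Il6 (1.44 ± 0.32, adjusted p = 0.0113) and Ptgs2, the inducible cyclooxygenase (1.47 ± 0.32, adjusted p = 0.0114), were higher as well, but lost the call without obstruction/vehicle replicate 1, at 1.24 and 1.28, on slides 2 and 3 alone, at 1.25 and 1.30, and with only the 6 arrays compared. Il6 was near background in sham/vehicle, so the size of its rise is uncertain, with values from 0.79 to 5.17 over the settings. Tnf did not pass the test (0.08 ± 0.07, adjusted p = 0.551), although it passed with the scanner software's log ratio, at 0.38.

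The macrophage and monocyte list had 20 of 23 genes higher and 0 lower (22 and 0 adjusted over the list alone; median 1.73, adjusted p = 2.58e-23 by camera and 0.0383 with an estimated correlation). Fcgr2a, an immunoglobulin receptor, rose by 4.26 ± 0.27, the lysozyme gene Lyz2 by 2.68 ± 0.12 and the myeloid adaptor gene Tyrobp by 2.68 ± 0.13. Of 24 neutrophil genes 14 were higher (15 adjusted over the list alone) and 0 lower, with adjusted p = 6.95e-09 by camera and adjusted p = 0.114 with an estimated correlation. S100a9, a subunit of calprotectin, rose by 5.58 ± 0.30, and its partner S100a8 by 5.27 in the fitted ratio (limma adjusted p = 4.19e-07). The brightest S100a8 probe was not well above background on any sham/vehicle array, and its Cy5 level was at least 259-fold higher. The other kept S100a8 probes gave smaller log2 differences, 3.435 and 1.694. The class II antigen presentation list had 7 of 12 genes higher, 0 lower (7 and 0 adjusted over the list alone), and held with an estimated correlation (adjusted p = 0.00842); its member Cd74 rose by 1.22 ± 0.09, a call lost with median centring (1.30). Neither the 11 B and plasma cell genes (0 higher, 0 lower; adjusted p = 0.726) nor the 25 T and NK cell genes (2 higher, 1 lower; adjusted p = 0.202) passed as lists.

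In the extracellular matrix list 27 of 36 genes were higher and 0 lower (32 and 0 adjusted over the list alone; median 1.31, adjusted p = 9.89e-22 by camera and 0.0383 with an estimated correlation), among them Col1a2 at 2.06 ± 0.12. Timp1, an inhibitor of matrix metalloproteinases, rose by 4.21 ± 0.11. The complement and acute phase list had 19 of 24 genes higher and 1 lower (21 and 1 adjusted over the list alone; adjusted p = 0.0427 with an estimated correlation), with the complement component C3 at 2.84 ± 0.17 and the iron-siderophore binder Lcn2 at 3.73 ± 0.17. The hypoxia list had 17 of 24 genes higher and 0 lower (20 and 0 adjusted over the list alone; adjusted p = 0.0383 with an estimated correlation), with adrenomedullin, Adm, at 2.60 ± 0.17 and lactate dehydrogenase A, Ldha, at 2.10 ± 0.09. Hmox1, the inducible heme oxygenase, rose by 2.42 ± 0.12 (adjusted p = 9.34e-08). Its antioxidant list had 11 of 26 genes higher and 1 lower (13 and 2 adjusted over the list alone), a call lost with an estimated correlation (adjusted p = 0.0983). Of 36 cell cycle genes, 5 were higher and 1 lower, both over all probes and adjusted over the list alone, and the list's camera call (adjusted p = 0.00822) was lost with an estimated correlation (adjusted p = 0.296). Cdk1, the mitotic kinase, rose by 0.55 ± 0.09 (call lost with median centring, 0.62), while Mki67, a marker of cycling cells, did not pass (0.13 ± 0.13, adjusted p = 0.625).

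Markers of other tissues differed between the same arrays. Of 12 seminal vesicle and coagulating gland genes, 7 were higher and 0 lower (7 and 0 adjusted over the list alone; median 3.10, adjusted p = 0.00842 with an estimated correlation). Svs6 rose by 6.78 ± 0.31, with Cy5 saturated on 2 obstruction/vehicle arrays, and Svs3a by 6.25 ± 0.13. Svs7 and Spink1l rose by 5.78 and 5.97 in the fitted ratio; neither was well above background on a sham/vehicle array, and their Cy5 levels were at least 326-fold and 279-fold higher. Serpina5, the protein C inhibitor, rose by 6.31 ± 0.31. Svs4 rose by 4.78 ± 0.20 in the ratio, with Cy5 saturated on 2 obstruction/vehicle arrays and 1 sham/vehicle array; Cy5 alone gave 0.47, which did not pass. Its Cy3 intensity, from sham/vehicle RNA throughout, averaged 140400 on sham/vehicle arrays and 8304 on obstruction/vehicle arrays. Close paralogs among the Svs, Spink and Scgb1d genes share sequence, so which member a probe reads is uncertain. Of 10 urothelial genes 4 were higher and 1 lower (5 and 1 adjusted over the list alone; adjusted p = 0.17 with an estimated correlation), with uroplakin Upk3a at 3.30 ± 0.19 and keratin Krt7 at 2.96 ± 0.21. In the nerve and Schwann cell list 11 of 19 genes were higher and 0 lower (16 and 0 adjusted over the list alone; adjusted p = 0.0983 with an estimated correlation), and peripherin, Prph, rose by 2.60 ± 0.17.

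The skeletal muscle list had 10 of 20 genes lower and 1 higher (11 and 2 adjusted over the list alone; median -0.68, adjusted p = 0.00842 with an estimated correlation). Parvalbumin, Pvalb, fell by 2.57 ± 0.30 on the log2 scale, the mitochondrial creatine kinase Ckmt2 by 2.46 ± 0.41, the enolase Eno3 by 2.10 ± 0.12, the myosin heavy chain Myh4 by 2.08 ± 0.23 and the light chain Myl11 by 2.06 ± 0.12. Wfdc3, a whey acidic protein family member, changed by -2.89 ± 0.11 (adjusted p = 1.49e-08). Probasin, Pbsn, an androgen-regulated secretory protein of the rat prostate, fell by 1.37 ± 0.15 (adjusted p = 0.000129; measured on 2 obstruction/vehicle arrays), a call lost with median centring (-0.995). The 27 androgen-regulated genes did not move as a list, with 3 higher, 6 lower (3 and 8 adjusted over the list alone) and adjusted p = 0.194.

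In all, limma called 4191 of 36098 probes in this comparison, 2583 higher and 1608 lower, and 1306 of them differed at least 2-fold, 1142 higher and 164 lower. Of all probes, 24.7% had groups that did not overlap, where chance gives 10% for arrays without slide effects. With the replicate block the count was 9125. Leaving out obstruction/vehicle replicate 2 gave 7196, sham/vehicle replicates 2 and 3 2426 and 2403, and obstruction/vehicle replicate 3 2639. Median centring in place of loess called 1613 higher and 175 lower, the scanner software's log ratio 5928 and 8552, and Cy5 alone 4442 and 7296. Camera called 27 of 34 lists (26 up, 1 down), and 8 held with an estimated correlation: seminal vesicle, macrophage, extracellular matrix, complement, class II presentation, smooth muscle and hypoxia genes up and skeletal muscle genes down. With both the block and an estimated correlation 0 lists passed, the smallest adjusted p being 0.0903 for skeletal muscle. With the block alone the prostate secretory epithelium list (9 of 28 higher, 5 lower; 9 and 6 adjusted over the list alone), called at adjusted p = 0.0473, was lost (adjusted p = 0.12).

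**Figure D1:**
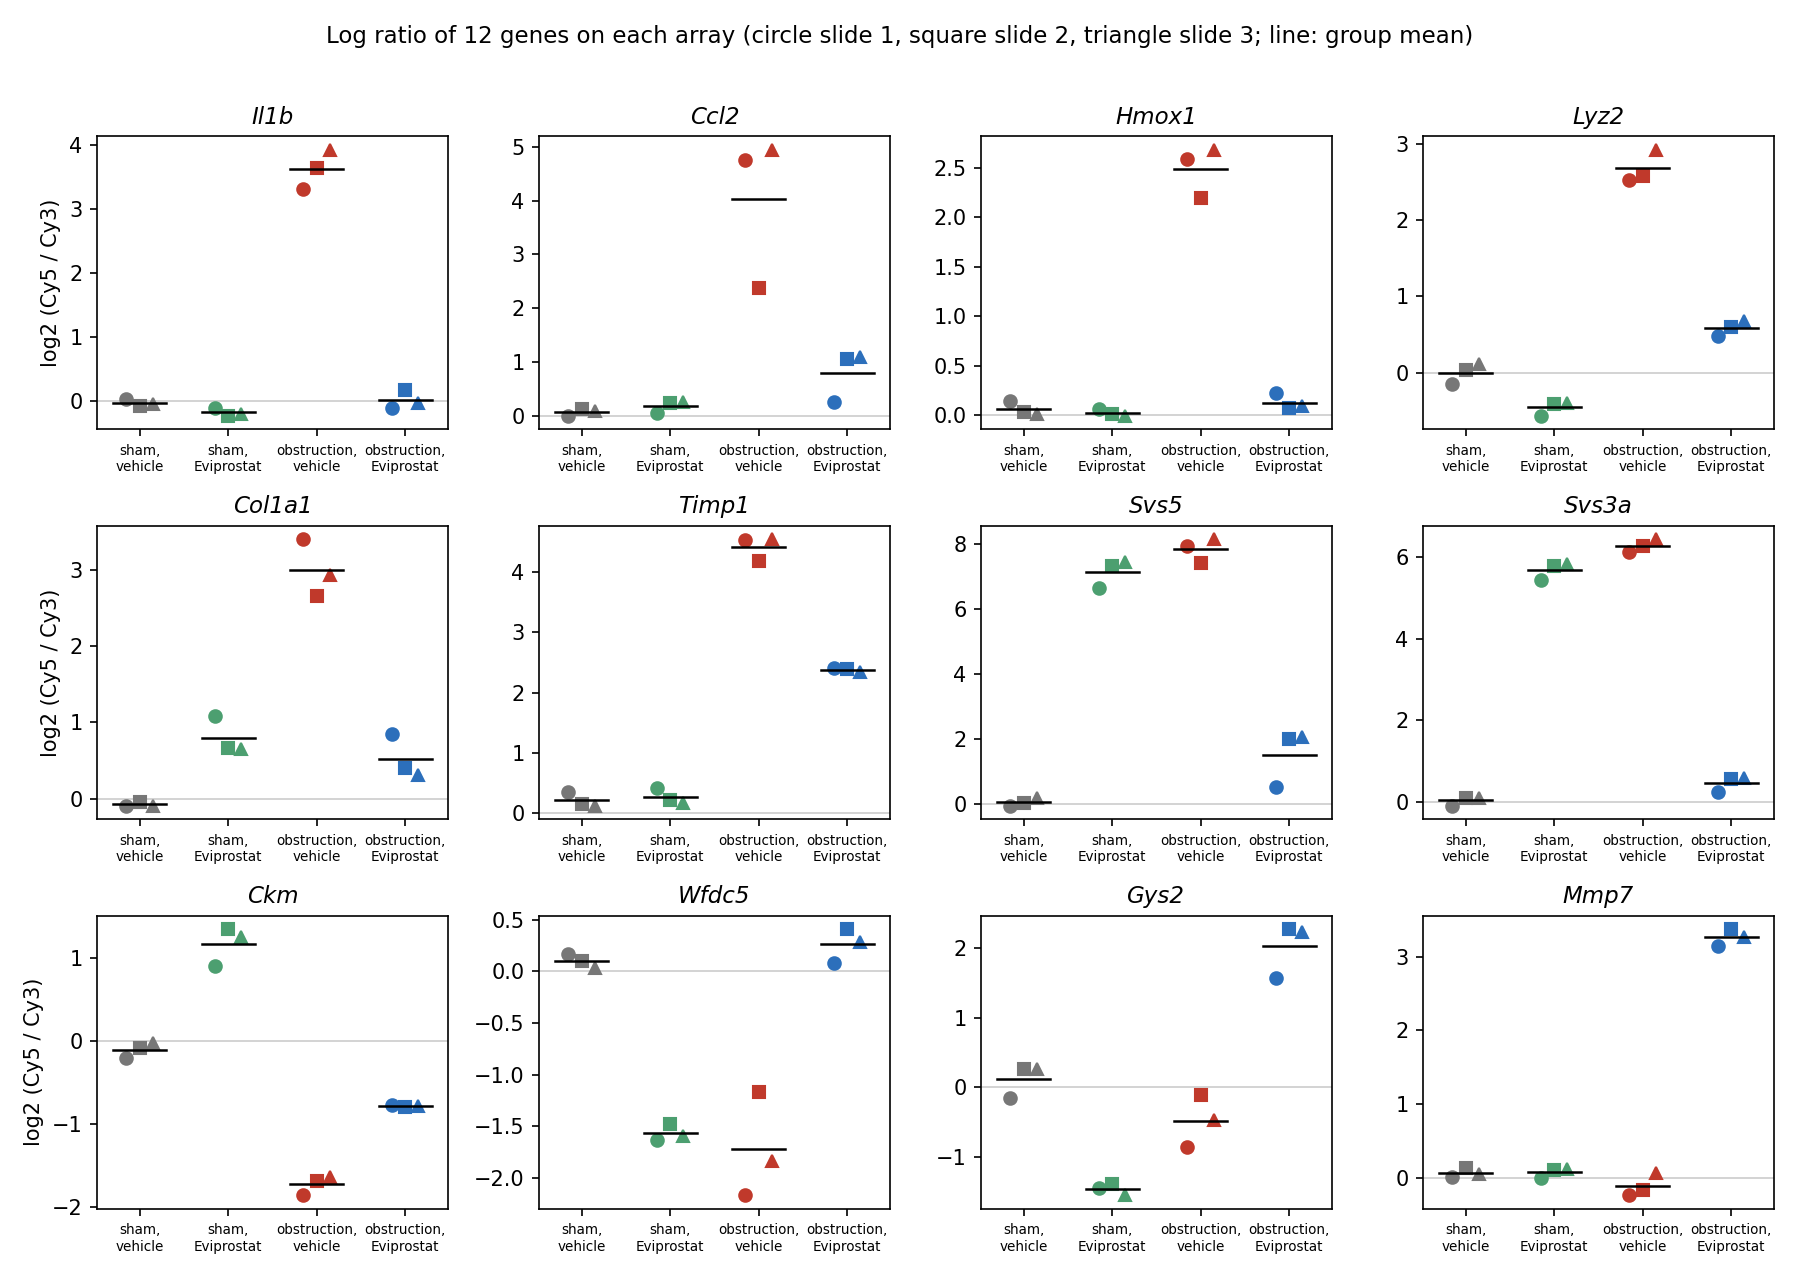
Log2 ratio of Cy5 to Cy3 for 12 genes, with 1 point per array (circle slide 1, square slide 2, triangle slide 3) and a line at each group's mean; the y axes differ between panels. Il1b and Hmox1 were high on the 3 obstruction/vehicle arrays alone, Svs5 and Svs3a were high in sham/Eviprostat and obstruction/vehicle, and Timp1 lay at 2.38 in obstruction/Eviprostat against 4.42 in obstruction/vehicle.

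Eviprostat was then compared with vehicle in obstructed rats. As lists, hypoxia, class II presentation and seminal vesicle genes were lower with Eviprostat, with the tests given below. These list calls held with an estimated correlation but not with the replicate block as well. Il1b was 12.3-fold lower (-3.62 ± 0.14, adjusted p = 1.8e-08 by limma) and Col1a1 5.56-fold lower (-2.47 ± 0.19, adjusted p = 6.32e-06), each on its brightest probe. Mmp7, the metalloproteinase matrilysin, was 10.4-fold higher (3.38 ± 0.10, adjusted p = 1.85e-09; probe at chromosome 8, 4533647 to 4533706 on rn3). Each of these 3 genes moved the same way on all 3 slides. Il1b differed by -8.72 in Cy5 alone.

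Cxcl2 fell by 7.05 ± 0.21 on the log2 scale, Cxcl1 by 4.76 ± 0.42 and Ccl2 by 3.22 ± 0.51 (adjusted p = 0.00164). Of 30 chemokine genes 13 were lower and 1 higher (18 and 2 adjusted over the list alone; adjusted p = 0.116 with an estimated correlation). Of 24 cytokine genes 8 were lower and 0 higher (13 and 0 adjusted over the list alone; adjusted p = 0.116 with an estimated correlation). Nos2 fell by 1.29 ± 0.24 (adjusted p = 0.00432). Il6 fell by 1.42 ± 0.32 in the fitted ratio (adjusted p = 0.0138) and Ptgs2 by 1.37 ± 0.32 (adjusted p = 0.0195). Il6 was not well above background on an obstruction/Eviprostat array, and its Cy5 level was at least 3.91-fold lower. The Il6 call was lost without obstruction/vehicle replicate 1 or 3 (log2 differences -1.23 and -1.09) and without obstruction/Eviprostat replicate 2 or 3 (-1.41 and -1.42). The Ptgs2 call was lost without the same 4 arrays (-1.18, -1.02, -1.42 and -1.36) and without obstruction/Eviprostat replicate 1 (-1.33). Both calls were also lost on slides 2 and 3 alone (-1.25 and -1.14) and with only the 6 arrays compared. Tnf did not pass (-0.07 ± 0.07, adjusted p = 0.624), although it passed with the scanner software's log ratio (-0.41) and in Cy5 alone (-0.50).

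In the macrophage and monocyte list 19 of 23 genes were lower and 0 higher (21 and 0 adjusted over the list alone; median -1.34, adjusted p = 0.064 with an estimated correlation). Tyrobp fell by 2.43 ± 0.13 and Lyz2 by 2.10 ± 0.12. Of 24 neutrophil genes 14 were lower and 0 higher (15 and 0 adjusted over the list alone; adjusted p = 0.116 with an estimated correlation), with S100a9 down by 5.68 ± 0.30 and S100a8 at -5.24 in the fitted ratio of its brightest probe, where its Cy5 level was at least 249-fold lower. The other kept S100a8 probes gave smaller log2 differences, -3.384 and -1.725. Class II presentation held with an estimated correlation (7 of 12 lower, 0 higher; 8 and 0 adjusted over the list alone; adjusted p = 0.0135), and Cd74 fell by 1.32 ± 0.09 (call lost with median centring, -1.41). So did the hypoxia list (16 of 24 lower, 0 higher; 19 and 0 adjusted over the list alone; adjusted p = 0.0483), with Adm down by 2.87 ± 0.17 and Ldha by 1.92 ± 0.09. The extracellular matrix list had 23 of 36 genes lower and 0 higher (28 and 0 adjusted over the list alone; adjusted p = 0.0775 with an estimated correlation), with Col1a2 at -1.83 ± 0.12. Timp1 fell by 2.05 ± 0.11, to a mean log2 ratio of 2.38 ± 0.04 (SD) against 0.21 ± 0.12 in sham/vehicle. C3 changed by -3.01 ± 0.17, Lcn2 by -4.02 ± 0.17 and Hmox1 by -2.36 ± 0.12.

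Of 12 seminal vesicle genes 7 were lower and 0 higher, over all probes and adjusted over the list alone (adjusted p = 0.0135 with an estimated correlation). Svs5, saturated on 2 of the 3 obstruction/vehicle arrays, changed by -6.31 ± 0.35, Svs3a by -5.83 ± 0.13, Svs4, also saturated on 2 of them, by -5.01 ± 0.20 (-0.70 and not past the threshold in Cy5 alone) and Serpina5 by -6.47 ± 0.31. Scgb1d2, a secretoglobin, fell by 4.82 ± 0.10. Serpina5 and Scgb1d2 are not among the listed seminal vesicle genes. Of 10 urothelial genes 5 were lower and 1 higher, over all probes and adjusted over the list alone (adjusted p = 0.159 with an estimated correlation), with Upk3a down by 3.63 ± 0.19.

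Of 36 cell cycle genes 13 were lower and 1 higher (23 and 1 adjusted over the list alone), a list call lost with an estimated correlation (adjusted p = 0.0984). Cdk1 changed by -1.32 ± 0.09 (adjusted p = 2.16e-06). Mki67 changed by -0.47 ± 0.13 (adjusted p = 0.0407) and lost the call without obstruction/vehicle replicate 1 (-0.50) or 3 (-0.39), without obstruction/Eviprostat replicate 2 (-0.41) or 3 (-0.36), and with only the 6 arrays compared. Genes higher with Eviprostat included Gys2, the liver form of glycogen synthase (2.51 ± 0.21), Wfdc5 (1.98 ± 0.20), Wfdc3 (1.95 ± 0.11), the androgen-regulated protease Tmprss2 (1.47 ± 0.19) and Pbsn (1.46 ± 0.15, with Pbsn measured on 2 obstruction/vehicle arrays and saturated on 2 obstruction/Eviprostat arrays). The unfolded protein response list had 6 of 20 genes higher and 2 lower, over all probes and adjusted over the list alone (adjusted p = 0.00042 by camera and adjusted p = 0.166 with an estimated correlation). Its members Dnajc3 and Hyou1, chaperone proteins of the endoplasmic reticulum, rose by 1.00 ± 0.10 and 0.94 ± 0.09. With median centring the calls of Mki67 (-0.64), Tmprss2 (1.46), Pbsn (1.26), Dnajc3 (0.99) and Hyou1 (0.95) were lost.

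In this comparison limma called 3536 probes, 1409 higher and 2127 lower, and 1070 differed at least 2-fold, 131 higher and 939 lower. Of all probes, 24.4% had groups that did not overlap, where chance gives 10% for arrays without slide effects. The count was 8494 with the replicate block, 6374 without obstruction/vehicle replicate 2, 2331 without obstruction/vehicle replicate 3, and 1898 and 1890 without obstruction/Eviprostat replicates 2 and 3. Median centring called 132 higher and 1197 lower, the scanner software's log ratio 7821 and 5700, and Cy5 alone 6102 and 4268. Camera called 26 lists (2 up, 24 down). The skeletal muscle list was called up, a call lost with median centring, with the 19 spots left out and with an estimated correlation. Pvalb, Ckmt2, Eno3, Myh4 and Myl11 differed by 1.58, 1.70, 1.19, 0.59 and 1.07. Only the hypoxia, seminal vesicle and class II presentation lists held with an estimated correlation. With the block as well 0 lists passed, at adjusted p = 0.219 for each of these 3.

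**Figure D2:**
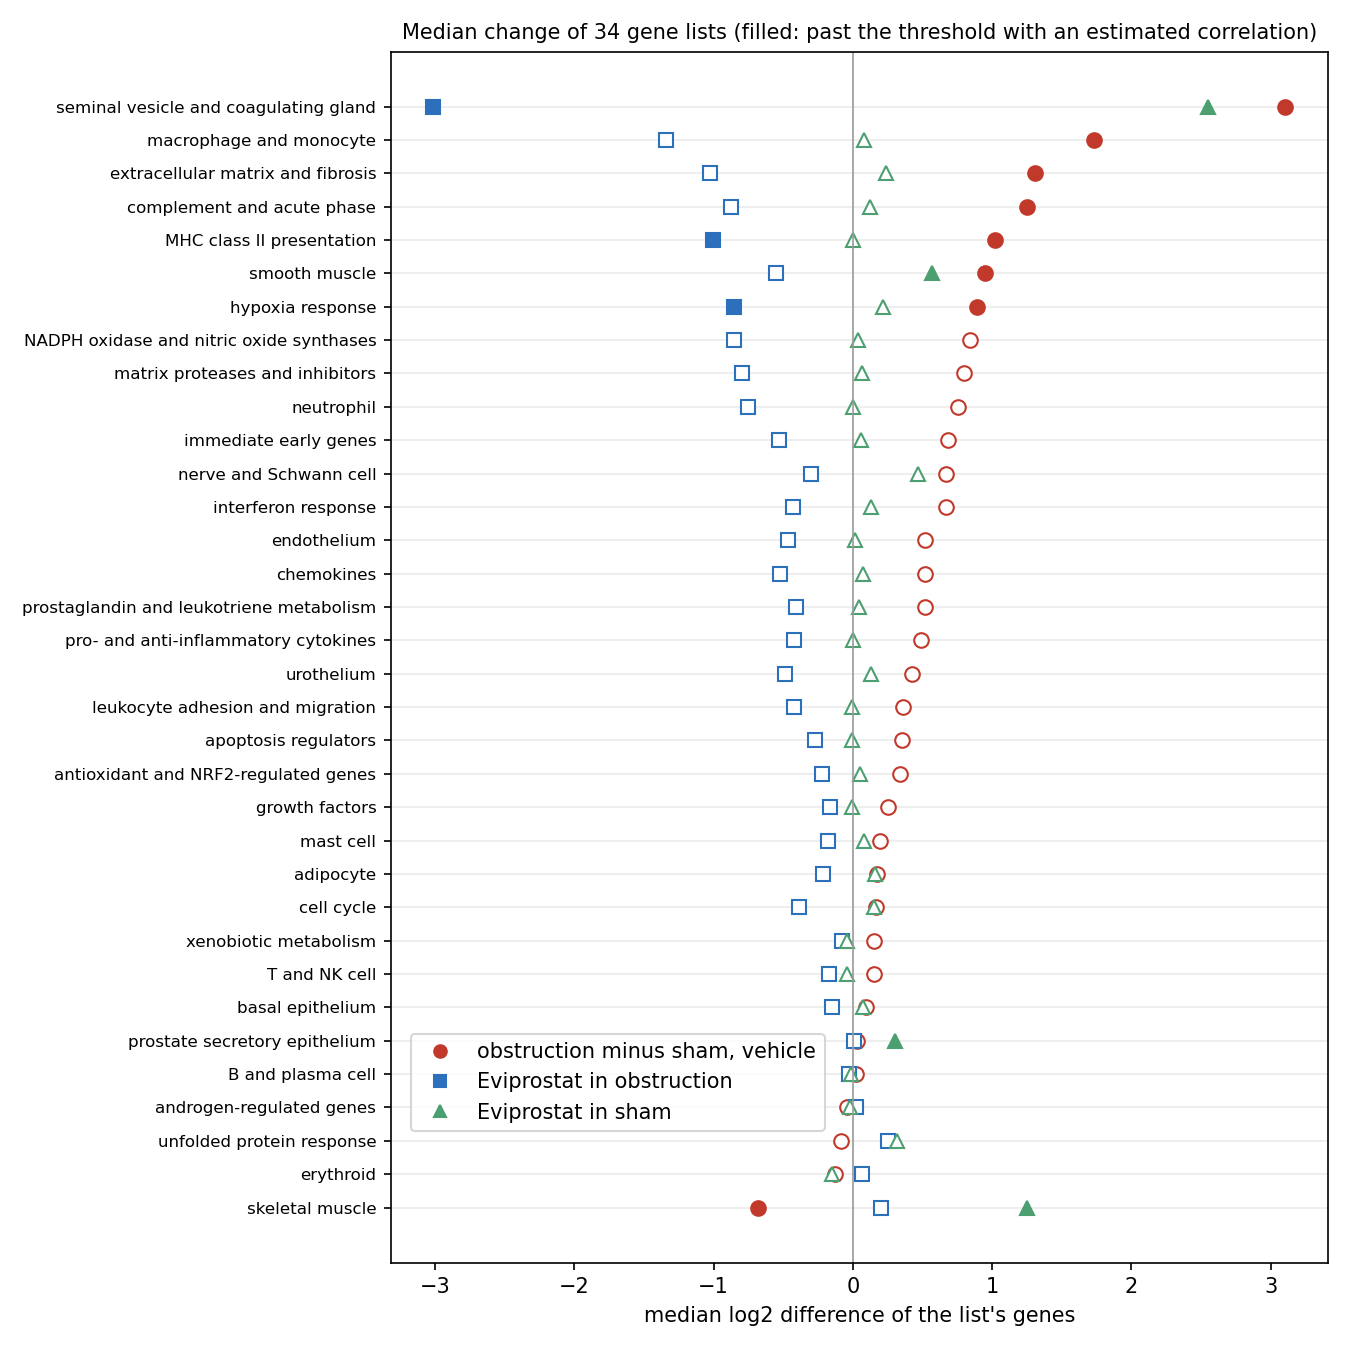
Median log2 difference of the measured genes of 34 gene lists (x axis) in 3 comparisons: obstruction minus sham under vehicle (circles), Eviprostat minus vehicle in obstructed rats (squares) and in sham rats (triangles). Filled symbols passed camera with an estimated correlation; the macrophage and monocyte median was 1.73 under obstruction and -1.34 with Eviprostat in obstruction, and the skeletal muscle median was 1.25 with Eviprostat in sham rats.

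The changes that obstruction brought were next followed under Eviprostat, the question the series states. Of 855 genes changed at least 2-fold by obstruction, 757 higher and 98 lower, 847 (99.1%) had a difference of opposite sign between obstruction/Eviprostat and obstruction/vehicle. For 736 genes the opposite change passed the threshold, and for 2 genes a change of the same sign did. The genes higher under obstruction, with a median of 1.47, had a median change of -1.34 with Eviprostat, and the genes lower under obstruction, with a median of -1.22, had 0.92. The opposite share was 99.2%, 93.1% and 99.3% on slides 1, 2 and 3, and 99.0% of 862 genes with the replicate block.

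Both differences use the obstruction/vehicle arrays, which gives opposite signs by itself. In simulated unchanged groups that shared such arrays, 84.6% of as many top genes had opposite signs, with a median of -0.24. The simulated spread was that between arrays of a group. It left out differences between the animals pooled in each group, so it gives no chance value for a deviating pool. Genes chosen without an obstruction/vehicle array and then measured against that array alone had opposite signs in 97.6%, 89.8% and 99.1% for replicates 1, 2 and 3, with medians of -1.55, -0.60 and -1.82 for the genes higher. Over all probes the correlation of the 2 comparisons was -0.917 (simulated -0.501) and the covariance -0.166 (simulated -0.0129). Of the probes called higher under obstruction 1821 were called lower with Eviprostat, against 152 for independent lists, and 900 went from lower to higher, against 62.8. Part of these excesses comes from the shared arrays. Between obstruction/Eviprostat and sham/Eviprostat, which share none of those arrays, 421 of the 855 genes (49.2%) kept the sign they had under vehicle, with 53 past the threshold in that sign and 53 in the other.

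**Figure D3:**
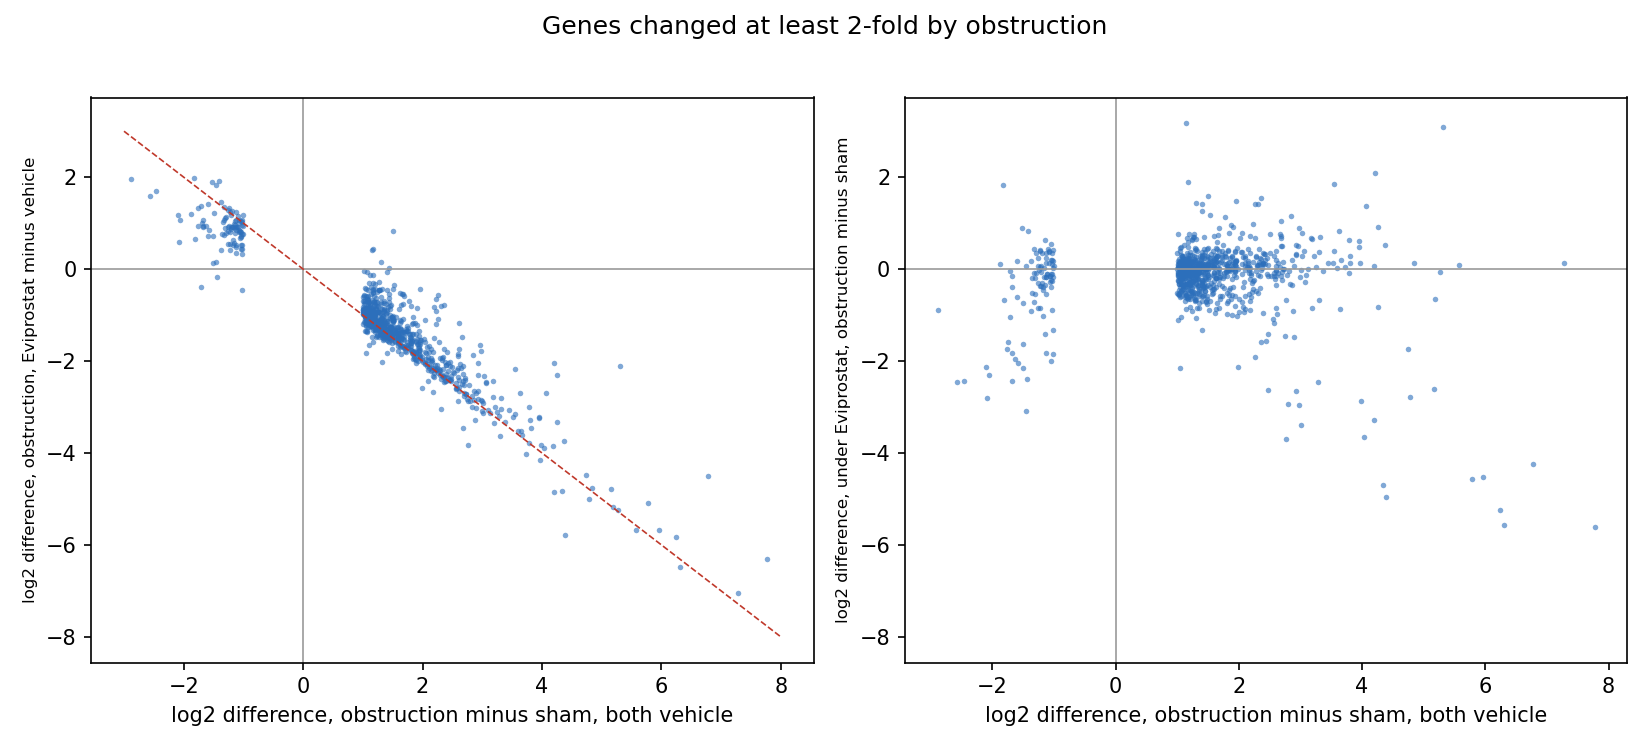
Genes changed at least 2-fold by obstruction under vehicle, 1 point per gene. The x axis is the log2 difference obstruction minus sham under vehicle; the y axis is the log2 difference Eviprostat minus vehicle in obstructed rats (left, with a dashed line where both differences cancel) and obstruction minus sham under Eviprostat (right). On the left 847 of 855 genes lie on the opposite side of 0, and on the right 421 lie on the same side.

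Eviprostat was also compared with vehicle in sham-operated rats, which asks what it does without obstruction. As lists, skeletal muscle and seminal vesicle genes were higher with Eviprostat, with the tests given below, and Il1b, Ccl2 and Cxcl1 did not pass. Svs5 was 135-fold higher (7.08 ± 0.35, adjusted p = 8.03e-07 by limma) and Svs3a 50.5-fold higher (5.66 ± 0.13, adjusted p = 4.11e-10). Ckm, muscle creatine kinase, was 2.41-fold higher (1.27 ± 0.11, adjusted p = 0.000115; probe at chromosome 1, 78850529 to 78850588 on rn3). All 3 genes were higher on each slide, and Svs5 differed by 11.44 in Cy5 alone.

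The seminal vesicle list had 7 of 12 genes higher and 0 lower, over all probes and adjusted over the list alone (median 2.55, adjusted p = 0.00103 with an estimated correlation). Svs6 rose by 6.51 ± 0.31 and Serpina5 by 5.39 ± 0.31. Svs7 and Spink1l rose by 5.26 and 4.80 in the fitted ratio, and their Cy5 levels were at least 63.6-fold and 37.2-fold higher. The prostate secretory epithelium list had 8 of 28 genes higher and 0 lower (11 and 1 adjusted over the list alone; adjusted p = 0.0182 with an estimated correlation, and 0.184 with the block as well). Andpro, an androgen-regulated protein, rose by 5.23 ± 0.21 and Wfdc21 by 3.78 ± 0.20, and Scgb1d2 was 18.4-fold higher (adjusted p = 4.11e-10). In the skeletal muscle list 13 of 20 genes were higher and 0 lower (16 and 0 adjusted over the list alone; median 1.25, adjusted p = 4.34e-05 with an estimated correlation), with Myl11 at 1.33 ± 0.12 and the troponin Tnni2 at 1.31 ± 0.12. Of 18 smooth muscle genes 5 were higher and 0 lower (10 and 0 adjusted over the list alone; adjusted p = 0.0182 with an estimated correlation, and 0.121 with the block as well). The actinin gene Actn1 rose by 1.01 ± 0.13 on its brightest probe, while its 2 other probes gave 0.19 and 0.15.

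Of 19 nerve and Schwann cell genes 8 were higher and 0 lower (11 and 0 adjusted over the list alone; adjusted p = 1.61e-14 by camera and adjusted p = 0.115 with an estimated correlation), with Prph at 1.77 ± 0.17 and neuropeptide Y, Npy, at 1.42 ± 0.14. Egf, epidermal growth factor, rose by 1.41 ± 0.09. Of 20 unfolded protein response genes 1, Hyou1, was higher (0.60 ± 0.09) and 0 were lower (6 and 0 adjusted over the list alone; adjusted p = 0.115 with an estimated correlation). Of 24 hypoxia genes 2 were higher and 0 lower (6 and 1 adjusted over the list alone; adjusted p = 0.343 with an estimated correlation), with Ldha at 0.76 ± 0.09. Genes lower with Eviprostat included the membrane glycoprotein Emb, which fell by 1.85 ± 0.14, the synaptic vesicle protein Sv2b by 1.74 ± 0.21, Wfdc5 by 1.67 ± 0.20, Plac8 by 1.60 ± 0.10 and Gys2 by 1.59 ± 0.21.

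Among the genes fixed by name, Ccl2 differed by 0.11 ± 0.51 (adjusted p = 0.987), Cxcl1 by -0.05 ± 0.42, Il1b by -0.15 ± 0.14, Hmox1 by -0.04 ± 0.12, Ptgs2 by 0.05 ± 0.32, Nos2 by 0.01 ± 0.24, Tnf by -0.08 ± 0.07, Pbsn by -0.09 ± 0.13 and Mki67 by 0.16 ± 0.13. None of these 9 passed, with limma adjusted p between 0.812 and 0.998, and Il6 was near background in both groups. Col1a1 passed at 0.88 ± 0.19 (adjusted p = 0.0448), and the call was lost when any 1 of the 6 arrays was left out, at values between 0.74 and 0.95, and with median centring (0.89), a normexp offset of 10 (0.84) or an intensity trend with a robust prior.

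Limma called 552 probes here, 314 higher and 238 lower, and 145 differed at least 2-fold, 121 higher and 24 lower. Of all probes, 19.04% had groups that did not overlap, where chance gives 10% for arrays without slide effects. The replicate block gave 2282 and array weights 7585. Leaving out sham/vehicle replicate 1, 2 or 3 gave 341, 243 or 231 and leaving out sham/Eviprostat replicate 2 or 3 gave 242 or 260. Median centring called 62 higher and 2 lower, and with it the calls of Ckm (1.28), Myl11 (1.32), Tnni2 (1.31), Actn1 (1.03), Prph (1.85), Npy (1.55), Egf (1.44), Hyou1 (0.58), Ldha (0.78), Emb (-1.89), Sv2b (-1.80), Wfdc5 (-1.70), Plac8 (-1.64) and Gys2 (-1.73) were lost. The Ldha call was also lost with an intensity trend and a robust prior. Camera called 9 lists, all up, and 4 held with an estimated correlation (seminal vesicle, prostate secretory epithelium, skeletal muscle and smooth muscle); with the block as well, seminal vesicle (adjusted p = 0.0394) and skeletal muscle (adjusted p = 0.00104) passed.

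Obstruction under Eviprostat, against sham rats given Eviprostat, shares no Cy5 array with the comparison under vehicle. As lists, skeletal muscle and seminal vesicle genes were lower in the obstructed rats, with the tests given below, and Mmp7, Il1rn and Timp1 were higher. Mmp7 was 9.12-fold higher (3.19 ± 0.10, adjusted p = 5.43e-09 by limma), Il1rn rose by 3.10 ± 0.24 and Timp1 by 2.10 ± 0.11, and Lyz2 by 1.04 ± 0.12. The value of Il1rn is that of its brightest probe, and its other kept probe gave 0.705. The skeletal muscle list had 14 of 20 genes lower and 0 higher (18 and 0 adjusted over the list alone; adjusted p = 2.17e-05 with an estimated correlation and 0.000728 with the block as well), with Myl11 down by 2.31 ± 0.12 and Ckm by 1.95 ± 0.11. The seminal vesicle list had 7 of 12 genes lower and 0 higher (7 and 1 adjusted over the list alone; adjusted p = 0.00355 with an estimated correlation and 0.0908 with the block as well), with Svs5 at -5.62 ± 0.35, Svs3a at -5.24 ± 0.13 and Serpina5 at -5.56 ± 0.31. Of 36 cell cycle genes 5 were lower and 0 higher (16 and 0 adjusted over the list alone; adjusted p = 0.0602 with an estimated correlation), and Cdk1 fell by 0.94 ± 0.09. Col1a1 (-0.28 ± 0.19, adjusted p = 0.642), Il1b (0.19 ± 0.14), Hmox1 (0.11 ± 0.12) and Ccl2 (0.62 ± 0.51) did not pass. In other settings Ccl2 passed in 7, with values up to 1.66 in Cy5 alone and 0.72 with the 19 bright spots left out of the background fit, Col1a1 passed in 3, among them the scanner software's log ratio (-0.33), and Il1b in 1, array weights (0.26).

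Here limma called 823 probes, 350 higher and 473 lower, and 204 differed at least 2-fold, 49 higher and 155 lower. Of all probes, 21.7% had groups that did not overlap, where chance gives 10% for arrays without slide effects. The replicate block gave 3157 and array weights 9650. Leaving out sham/Eviprostat replicate 2 or 3 gave 372 or 387, and leaving out obstruction/Eviprostat replicate 2 or 3 gave 352 or 355. Median centring called 33 higher and 107 lower, and the calls of Ckm (-1.96), Myl11 (-2.31), Lyz2 (1.07) and Cdk1 (-0.99) were lost with it. Camera called 10 lists (3 up, 7 down), of which the skeletal muscle and seminal vesicle lists held with an estimated correlation, and fry called 4. With the block the nerve and Schwann cell list, called at adjusted p = 0.0244, was lost (adjusted p = 0.0572).

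The last comparison tested whether the effect of Eviprostat differed between obstructed and sham rats. Seminal vesicle genes had a more negative difference with Eviprostat in obstructed rats (7 of 12, with 0 more positive, over all probes and adjusted over the list alone; adjusted p = 0.00667 with an estimated correlation), a list call lost with the block as well (adjusted p = 0.148). Svs5, saturated in Cy5 on 2 obstruction/vehicle arrays, differed by -13.39 ± 0.50 between the 2 effects (adjusted p = 1.88e-08 by limma; -21.54 in Cy5 alone), Il1b by -3.47, Ccl2 by -3.33, Col1a1 by -3.35 and Hmox1 by -2.32 ± 0.16. Wfdc5 and Gys2, which fell with Eviprostat in sham rats and rose with it in obstructed rats, differed by 3.65 ± 0.28 and 4.10. For Ckm the difference was -0.33 and did not pass, although it passed in 4 other settings: slides 2 and 3 alone (-0.49), array weights (-0.47), and the scanner software's log ratio and the series' value table (-0.35 each). The Ccl2 call was lost on slides 2 and 3 alone (-2.73). Of 20 skeletal muscle genes 4 differed downward and 0 upward (13 and 0 adjusted over the list alone; adjusted p = 0.00667 with an estimated correlation and 0.0496 with the block as well). For the muscle genes Pvalb, Ckmt2, Eno3, Myh4 and Myl11 the difference was 0.116, 0.017, -0.025, -0.721 and -0.255, none past the limma threshold without the block. Each of these genes had a positive difference with Eviprostat in sham and in obstructed rats. The extracellular matrix list had 23 of 36 genes more negative and 0 more positive (26 and 0 adjusted over the list alone), and the macrophage and monocyte list 15 of 23 and 0 (20 and 0 adjusted over the list alone). Both calls were lost with an estimated correlation (adjusted p = 0.0697 for each).

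Limma called 3127 probes in this test, 1363 with a more positive and 1764 with a more negative effect in obstructed rats, and 1508 differed at least 2-fold, 342 upward and 1166 downward. The replicate block gave 7919 and array weights 7101. The count was 5857 without obstruction/vehicle replicate 2, 1841 and 1838 without sham/vehicle replicates 2 and 3, 2082 without sham/Eviprostat replicate 2, and 1819 and 1881 without obstruction/Eviprostat replicates 2 and 3. Median centring called 107 upward and 910 downward, the scanner software's log ratio 6538 and 5173, and Cy5 alone 4822 and 3795. Camera called 25 lists, all down, and 5 held with an estimated correlation (seminal vesicle, skeletal muscle, class II presentation, hypoxia and smooth muscle genes). With the block as well only skeletal muscle passed (adjusted p = 0.0496), and the adjusted p was 0.148 for seminal vesicle and 0.165 for each of the 3 others.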

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

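The tests of explanations given here were chosen only after the results were seen, except for the splits of the arrays and the genes chosen without an array, which were set before. The interaction of obstruction and Eviprostat was drawn out because the effect of Eviprostat differed between the groups: limma called 3127 probes and camera 25 lists. The Cy3 channel carried sham/vehicle RNA on every array and was not compared between groups at first. When it was, 103 probes differed in Cy3 between obstruction/vehicle and sham/vehicle arrays, 91 higher and 12 lower.

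Seminal vesicle genes were high under obstruction and, without obstruction, under Eviprostat, and low again with both. The lower of the list's 2 medians was 2.54 with the 19 bright spots left out of the background fit, so the background fit does not account for the pattern. On slides 2 and 3 alone the lower median was 2.47. The scan day was balanced over the groups by design, so this value decides nothing about the scan day. Of the listed genes bright in some group and more than 10-fold dimmer in sham/vehicle, 6 of 6 (Svs1, Svs3a, Svs3b, Svs5, Svs6 and Svs7) rose in both comparisons, but they were chosen for being low in sham/vehicle, the control of both, so this count decides nothing. Semg1, also listed, was bright in all groups (mean Cy5 188500 in sham/vehicle) without saturated Cy5, and differed by -0.36 and 0.36 without passing. Svs4 was at 438900 in sham/vehicle and rose under obstruction by 4.78 in the ratio, but by 0.47 in Cy5 alone, which did not pass. Such high Cy5 levels in sham/vehicle could hide added tissue, which was not tested. The pattern was not confined to this list. Of the prostate secretory epithelium list, Scgb1d4 rose by 4.382 under obstruction and by 3.543 with Eviprostat in sham rats. It changed by -5.794 with Eviprostat in obstructed rats. Pbsn, of the same list, did not share the pattern, at -1.37, -0.085 and 1.46. That list had 9 of 28 genes higher and 5 lower under obstruction, and 8 and 0 with Eviprostat in sham rats. Unequal shares of secretory epithelium in the pools were not tested. Whether tissue of the seminal vesicle or coagulating gland was in 2 of the pools, or the prostate itself changed, stays open in pooled RNA.

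Genes higher under obstruction were lower again in obstructed rats given Eviprostat. Their median change was -1.36 with the 19 spots left out of the background fit, -1.34 on slides 2 and 3 alone and -1.47 with median centring, and -0.60 at the weakest when genes were chosen without obstruction/vehicle replicate 2 and measured against it. These values argue against the background fit, loess and a choice of genes on the noise of single arrays as the whole cause. The scan day was balanced over the groups by design, with 1 array of each group per slide. The array left out carried RNA of tissue pooled within the same group, so genes chosen on a deviating pool were not tested. The macrophage and monocyte list had a median of -1.34 with Eviprostat, so fewer immune cells in the pool might explain part of the change instead of lower expression per cell. Bulk RNA keeps this open, and counts of macrophages in sections would test it. Some markers of other tissues also rose under obstruction and fell with Eviprostat, such as Upk3a (3.30 and -3.63) and Cfd (3.79 and -3.01). The urothelial and adipocyte list calls were lost with an estimated correlation in both comparisons. Whether other tissue in the obstruction/vehicle pool contributed was not tested.

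Sham/vehicle RNA in Cy3 gave more signal beside obstruction RNA for 91 probes, and 88 of these were at least 2-fold higher in Cy5. Beside sham/Eviprostat RNA 11 probes differed in Cy3, all 11 higher and all 11 at least 2-fold higher in Cy5. Obstruction RNA in the reference alone would not give the gains on those arrays. A fixed share of Cy5 light read as Cy3 would give a constant ratio of the Cy3 gain to the Cy5 gain, but the 90th percentile of that ratio was 7.15 times the 10th over 89 probes, which argues against it. Obstruction RNA in the Cy3 reference would give probes of one gene the same ratio, and for 3 genes (Fcgr2a, Il1b and Slpi) the highest was 2.48 times the lowest in the median, which leaves it open. For Svs5, mean Cy3 rose from 364 to 1202 while mean Cy5 rose from 438 to 485600. Svs4 went the other way, with mean Cy3 of 140400 on sham/vehicle, 30510 on sham/Eviprostat and 8304 on obstruction/vehicle arrays, which makes its ratio larger. The 12 probes lower in Cy3 were not examined further. A dye swap would show whether the ratios of such genes may be too small or too large.

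Splits of the arrays into other groups gave fewer probes. In each comparison of 2 groups the real split was 1 of 10, and the highest other count was 0 probes against 4191, 3536, 552 and 823. The count of 0 against 736 genes moved back by Eviprostat follows from this, because such genes had to be called. In the other splits a real group difference would add to the spread within groups and lower the counts. These counts of 0 are therefore no test under the absence of an effect. For lists the real and highest other counts were 27 and 28 for obstruction, 26 and 26 for Eviprostat in obstruction, 9 and 8 for Eviprostat in sham rats, and 10 and 4 for obstruction under Eviprostat, so that 2, 2, 1 and 1 of the splits were as large. There are too few such splits for a share under 0.05. With an estimated correlation, the highest other count was 0 lists in each comparison, against 8, 3, 4 and 2. The same limit holds for these list counts. Among 100 random splits of the 12 arrays, 1 gave as many probes with an interaction as the real one, the real split itself, and the highest other count was 641. As many lists were called in 8 of 100 splits, the real one among them, with a highest other count of 27, so chance stays open for the 25 lists with an interaction. These random splits kept any real differences between the groups and ignored the slides. Camera with an estimated correlation was not run on them. They are therefore no test under the absence of an effect, and the count of lists decides nothing by itself.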

How the results depend on the processing

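The fits without the 19 bright spots, without the 3 arrays they lay on and on slides 2 and 3 alone, the tests on them and the comparison of sizes were chosen only after the results were seen. Aquantile left the log ratios as they were, the series' value table repeats the scanner software's log ratio and the slide block repeats the replicate block, so these 3 are not counted. Of 3295 values of 149 named results in 28 other settings, 3185 kept their sign and their side of the threshold, 69 lost the call, 15 gained it and 26 were of opposite sign, and 92 of the 131 results past the threshold kept the call in all settings. None of the results called changed direction. Their sizes moved more: 44 of the 131 differed from the fit by more than 1.5 times upward in Cy5 alone and 2 downward, 8 upward with the scanner software's log ratio and 9 downward without background subtraction. Il1b by obstruction ran from 3.51 to 8.59. The cause of the differences was not tested.

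Counts are given in the order obstruction, Eviprostat in obstruction, Eviprostat in sham rats, obstruction under Eviprostat and the interaction. With the replicate number as a block, or the slide, 9125, 8494, 2282, 3157 and 7919 probes were called, and with the scan day as a block 9232, 8560, 2357, 3371 and 7971. The scanner software's log ratio and the series' value table each called 14480, 13521, 3423, 4279 and 11711. Cy5 alone called 11738, 10370, 2119, 2470 and 8617, and median centring 1788, 1329, 64, 140 and 1017. A fold minimum of 2 kept 1306, 1070, 145, 204 and 1508. With the 19 spots left out the block fit called 14075, 13173, 3865, 4986 and 11648.

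Fits that moved some counts only were these. Leaving out the 19 spots gave 7718 and 6833 for obstruction and for Eviprostat in obstruction, and 5718 for the interaction; no background subtraction gave 7911, 7158 and 5830, and leaving out the 3 arrays 6412, 5461 and 5380. Only the 6 arrays compared gave 1834 and 1768. Array weights gave 7585, 9650 and 7101 for Eviprostat in sham rats, obstruction under Eviprostat and the interaction, and slides 2 and 3 alone 1135 and 2275 for the first 2 of these. Obstruction/vehicle ratios against 0 gave 9482 probes. Camera with an estimated correlation called 8, 3, 4, 2 and 5 lists, and fry called 4 lists for obstruction under Eviprostat.

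With 1 array left out, counts ran from 2403 to 7196 probes for obstruction, 1890 to 6374 for Eviprostat in obstruction, 231 to 537 for Eviprostat in sham rats, 352 to 730 for obstruction under Eviprostat and 1819 to 5857 for the interaction. Lists ran from 26 to 27, 25 to 26, 9 to 9, 8 to 10 and 25 to 26, and the opposite share of obstruction-changed genes from 89.8% to 99.1%.

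Sign changes lay within Eviprostat in sham rats and among differences near 0 that had not passed. Il6 (-0.004) turned to 0.046 with the scanner software's log ratio and with the series' value table, 0.004 without background subtraction, 0.048 in Cy5 alone, 0.007 without the 19 spots, with and without the block, 0.001 on slides 2 and 3 alone, 0.005 without the 3 arrays, and 0.005, 0.006 and 0.012 without sham/vehicle replicate 1, sham/vehicle replicate 3 and sham/Eviprostat replicate 2, its lowest value with 1 array left out being -0.023. Ptgs2 (0.05) turned to -0.129 with the software's log ratio and the value table, -0.001 without background subtraction, -0.028 with median centring and -0.380 in Cy5 alone. Nos2 (0.011) turned to -0.011 with the software's log ratio and the value table, -0.028 with median centring, -0.296 in Cy5 alone, -0.014 without the 19 spots, with and without the block, and -0.019, -0.007 and -0.005 without sham/vehicle replicate 3, sham/Eviprostat replicate 1 and sham/Eviprostat replicate 2, its highest with 1 array left out being 0.045. Pbsn (-0.085) turned to 0.066 with the software's log ratio and the value table and, with 1 array left out, ran from -0.189 to 0.022, the latter without sham/Eviprostat replicate 1. Cxcl1 (-0.045) turned to 0.002 in Cy5 alone and, with 1 array left out, ran from -0.096 to 0.054, the latter without sham/Eviprostat replicate 2.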

Other observations

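Obstruction under vehicle also moved genes of other kinds. Cfd, the adipocyte serine protease adipsin, rose by 3.79 ± 0.17 (adjusted p = 6.58e-08 by limma) and adiponectin, Adipoq, by 2.30 ± 0.43 (adjusted p = 0.00444). The Adipoq call was lost on slides 2 and 3 alone (1.92) and with only the 6 arrays compared, and its value ran from 1.46 to 5.09 over the settings. The adipocyte list had 6 of 17 genes higher and 1 lower, over all probes and adjusted over the list alone (adjusted p = 0.152 with an estimated correlation). The interferon-induced genes Ifit1 and Isg15 rose by 3.60 ± 0.27 and 1.96 ± 0.17, with 12 of 26 listed genes higher and 0 lower (16 and 0 adjusted over the list alone; adjusted p = 0.0542 with an estimated correlation). Of 26 immediate early genes 14 were higher and 0 lower (15 and 0 adjusted over the list alone; adjusted p = 0.0748 with an estimated correlation), with the transcription factor genes Junb at 2.43 ± 0.16 and Jun at 1.58 ± 0.11. In the smooth muscle list 11 of 18 genes were higher and 1 lower (12 and 1 adjusted over the list alone; adjusted p = 0.0383 with an estimated correlation), with the enteric actin Actg2 at 1.63 ± 0.15 (call lost with median centring, 1.68) and smoothelin, Smtn, at 1.12 ± 0.09.

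With Eviprostat in obstructed rats Cfd fell by 3.01, Ifit1 by 3.53, Isg15 by 1.53, Junb by 2.04, Jun by 1.51 and Actg2 by 1.17, all past the limma threshold. With median centring the calls of Isg15 (-1.67) and Actg2 (-1.15) were lost. Of 26 immediate early genes 12 were lower and 0 higher (14 and 0 adjusted over the list alone; adjusted p = 0.0984 with an estimated correlation), and of 26 interferon genes 9 were lower and 0 higher (10 and 0 adjusted over the list alone; adjusted p = 0.1 with an estimated correlation). Probes of one gene did not always give the same size: Il1b rose by 3.66 on its brightest probe and by 5.84 on another, and Col1a1 by 3.07, 1.71 and 1.51. Larger gaps were seen for Il1rn, at 5.31 and 1.58, and for S100a8, at 5.27, 3.435 and 1.69.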
